A study of Homo sapiens with 9 samples.

How the data were processed

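The series profiled chromatin in MCF7, an estrogen receptor-positive human breast cancer line, and in MCF7-LTED, its derivative kept long term without estrogen (called LTED here). Of the 9 samples described, 7 came with a list of intervals that was used here and 2 were LTED input libraries whose signal was not analysed here. Trimethylated lysine 36 of histone H3 (H3K36me3), a mark of transcribed gene bodies, was profiled by chromatin immunoprecipitation and sequencing in untreated MCF7, in MCF7 treated with estradiol (E2) for 45 minutes, and in LTED. In LTED, dimethylated lysine 4 of histone H3 (H3K4me2, found at promoters and enhancers), the homeodomain transcription factor PBX1, and open chromatin were also profiled. Open chromatin was measured by FAIRE, which isolates DNA little bound by nucleosomes, in 2 replicates.

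The values started from were the lists as deposited. For H3K36me3, H3K4me2 and FAIRE the deposited lists gave 1 score per interval, the authors' own value, with no score below 50. The scale of the score was given by no header or label, so scores were used to rank or select intervals within a list and to give medians within a list, and a ratio of medians has no fixed meaning. The names of the intervals were those written by the MACS peak caller, but the version, the aligner and the control library were not given in the sources used here for these lists. For PBX1 the deposited list gave summits of 1 bp, each with a signal, the height of the summit. MACS 1.4 and the hg19 build were named for PBX1 by the submitters' processing notes. For the other lists hg19 was taken from the names under which they were deposited. Each list belonged to 1 sample, so nothing was pooled before the lists were made. The number of sequenced reads was not given in the sources used here, so the depth of every library was unknown, and a longer list may rest on deeper sequencing.

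Intervals on chromosomes 1 to 22 and X were used. Between 12 and 65 intervals per list lay elsewhere and were left out. A start below 0, found for 1 interval in each MCF7 list, was set to 0. Positions are 1-based. An overlap needed at least 1 bp, and a PBX1 summit was extended by 100 bp on each side. FAIRE sites of both replicates were the merged regions holding a site of each replicate. The share of each H3K36me3 list's covered length shared with another, and the Jaccard index (shared over joint length), were computed from merged intervals.

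H3K36me3 was compared between conditions in 100 kb bins, as the percentage of each bin covered by intervals. A bin counted as gained or lost when the coverage differed by at least 25 percentage points. The plan made before the data were examined was to use gene bodies, gene lists and distances to genes, with these bins in their place where no annotation of hg19 was given. The annotation at hand was of GRCh38 and builds were not mixed, so no gene is named and all gene-based comparisons were left out. The tests, the size rule for bins and the rule for named regions were likewise chosen before the data were examined. That rule took the 10 bins with the largest gain and the 10 with the largest loss in LTED, ranked by the smaller of the differences to the MCF7 lists, and the 5 highest PBX1 summits.

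Overlaps between lists were tested one-sided by permutation. In each of 100 draws the intervals of one list were placed at random on their own chromosome, with gaps of the assembly not excluded. A second background moved each interval by up to 50 kb and so kept it in its neighbourhood. The smallest p that 100 draws can give is 0.0099. The settings with a reciprocal overlap or a minimum share of the site, and the simulated data, used 20 draws, whose smallest p is 0.0476. The length of a chromosome was taken as the highest coordinate in any list. Shares are given with exact (Clopper-Pearson) 95% binomial intervals, and ratios of medians with bootstrap 95% intervals from 1000 resamplings. Both cover counting error only. Each H3K36me3 condition, H3K4me2 and PBX1 had 1 library, so differences between conditions had no replicate check and no p-value is given for them. Correlations across bins describe the libraries, since neighbouring bins are not independent replicates. Nothing in the labels said that the FAIRE replicates came from separate cultures.

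The overlap procedure was tested on simulated data. As many sites as there were PBX1 summits (25483) were placed at random, and a share of them was planted on H3K4me2 regions. The recovered share was the excess over the mean of random placement. With 19.8% planted it was 19.9%, and with none planted it was 0.0379% (permutation p = 0.286). For the bins, all intervals of the most covered bins were removed from the untreated MCF7 list, which was otherwise left unchanged. All planted lost bins (100%) were recovered and 0 others were called, an outcome fixed by this construction. It held no noise between libraries and gives no error rate for the bin rule. Alternatives tried were lists restricted to a matched covered length, the stricter part of each list by score, autosomes only, joining of intervals within 1 kb, bins of 50 and 500 kb, summit windows of 0 and 500 bp, a reciprocal overlap of 50%, and each FAIRE replicate alone. A limit of 10 percentage points and the removal of chromosomes 17 and 20 were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.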

Results

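The 7 lists differed in size. H3K36me3 intervals numbered 71604 in untreated MCF7, 33570 in E2-treated MCF7 and 46471 in LTED, and covered 24.4, 17.8 and 15.9 Mb with median widths of 291, 468 and 269 bp. H3K4me2 in LTED gave 57368 regions over 21.7 Mb. FAIRE gave 44224 sites over 37.5 Mb in replicate 1 and 60361 sites over 54.9 Mb in replicate 2. PBX1 gave 25483 summits with heights from 9 to 779 and a median of 16. Read depth was unknown for every library, so the sizes of lists were not compared as amounts of a mark.

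The comparison of H3K36me3 between MCF7 and LTED asked how transcription-linked chromatin differed between cells sensitive to endocrine therapy and cells resistant to it. The LTED list shared little with either MCF7 list. Of LTED intervals, 11.0% (10.7 to 11.3%) met an untreated MCF7 interval and 9.83% (9.56 to 10.1%) met an E2-treated one, while 36.1% (35.6 to 36.6%) of E2-treated intervals met an untreated one. In length, untreated and E2-treated MCF7 shared 4.44 Mb (Jaccard index 0.118), untreated MCF7 and LTED 1.08 Mb (0.0276), and E2-treated MCF7 and LTED 1.53 Mb (0.0475). Each share exceeded random placement. LTED intervals met untreated ones 5.46 times as often as after placement on the same chromosome and 1.59 times as often as after local shifts. For LTED against E2-treated intervals these ratios were 7.18 and 2.12, and for E2-treated against untreated intervals 13.7 and 2.39 (permutation p = 0.0099 in each case). After local shifts, the ratio of LTED against E2-treated intervals was thus near that of the MCF7 pair. With the lists restricted to a matched covered length, 7.18% of LTED intervals met untreated ones.

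Merging the 3 H3K36me3 lists gave 127363 regions. Of these, 53158 lay in untreated MCF7 alone, 38628 in LTED alone and 18887 in E2-treated MCF7 alone, and 2149 lay in all of them. Regions found in both MCF7 lists were found in LTED more often than regions of a single MCF7 list. The share was 18.8% (18.1 to 19.6%, n = 11411) for regions in both, 5.38% (5.20 to 5.57%, n = 56183) for those in untreated MCF7 without E2-treated MCF7, and 10.7% (10.2 to 11.1%, n = 21141) for the converse. Regions in all lists had a median width of 1063 bp, against 260 bp for those in LTED alone, and wider regions meet other intervals more readily.

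Across the 14787 bins of 100 kb with an interval in any H3K36me3 list, coverage correlated at Pearson 0.800 (Spearman 0.676) between the MCF7 lists, at 0.392 (0.416) between untreated MCF7 and LTED, and at 0.397 (0.336) between E2-treated MCF7 and LTED. Without chromosomes 17 and 20 the Pearson values were 0.806, 0.357 and 0.406. Chromosomes 17 and 20 together held 15.2% of the covered length in untreated MCF7, 20.4% in E2-treated MCF7 and 11.96% in LTED. The highest coverage of any bin was 82.7% in untreated MCF7, 82.8% in E2-treated MCF7 and 25.1% in LTED. With the maximum in LTED so low, a gain of 25 points was reachable there only from a bin nearly free of the mark.

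H3K36me3 coverage was lower in LTED than in both MCF7 lists, by at least 25 points, in 17 bins, and higher in 0. Of the 17, 7 lay on chromosome 17, 7 on chromosome 20 and 3 elsewhere, with median coverages of 42.8% in untreated MCF7, 56.6% in E2-treated MCF7 and 7.90% in LTED. Against untreated MCF7 alone, 33 bins were lower and 0 higher. These counts moved to 98 and 7 with 50 kb bins, 1 and 0 with 500 kb bins, and 102 and 0 with intervals within 1 kb joined. Without chromosomes 17 and 20 they were 15 and 0. The bin with the largest loss, at 46300001 to 46400000 on chromosome 20 (hg19), was covered at 82.7% in untreated MCF7, 76.3% in E2-treated MCF7 and 10.3% in LTED. Its neighbour at 46200001 to 46300000 had 53.9%, 78.9% and 12.1%. Further losses on chromosome 20 lay at 45800001 to 45900000 (46.0%, 57.2% and 4.86%), at 47300001 to 47400000 (59.6%, 43.0% and 4.83%) and at 55700001 to 55800000 (47.1%, 60.8% and 11.8%).

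On chromosome 17 the largest loss was at 59400001 to 59500000 (hg19), covered at 60.1% in untreated MCF7, 62.9% in E2-treated MCF7 and 15.1% in LTED. The adjoining bin at 59300001 to 59400000 had 49.6%, 55.1% and 7.90%. The bins at 58500001 to 58600000 (42.1%, 75.1% and 9.47%) and at 58700001 to 58800000 (36.8%, 56.6% and 6.59%) were also among the 10 largest losses. The remaining one lay on chromosome 3 at 63900001 to 64000000 (34.3%, 34.2% and 2.46%). These 10 bins still ranked between percentiles 95.02 and 99.86 by LTED coverage among all 30359 bins, of which 12218 held an LTED interval. An untreated MCF7 interval lay in 8218 bins and an E2-treated one in 8303, so the LTED list spread a smaller covered length over more bins. No FAIRE site of either replicate lay in 7 of the 10, against 2 of the 10 largest gains given below. No such share over all bins is given here. The count of 17 became 3 without chromosomes 17 and 20, 32 with 50 kb bins and 1 with 500 kb bins. No library in a second culture was at hand to check these differences.

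**Figure D1:**
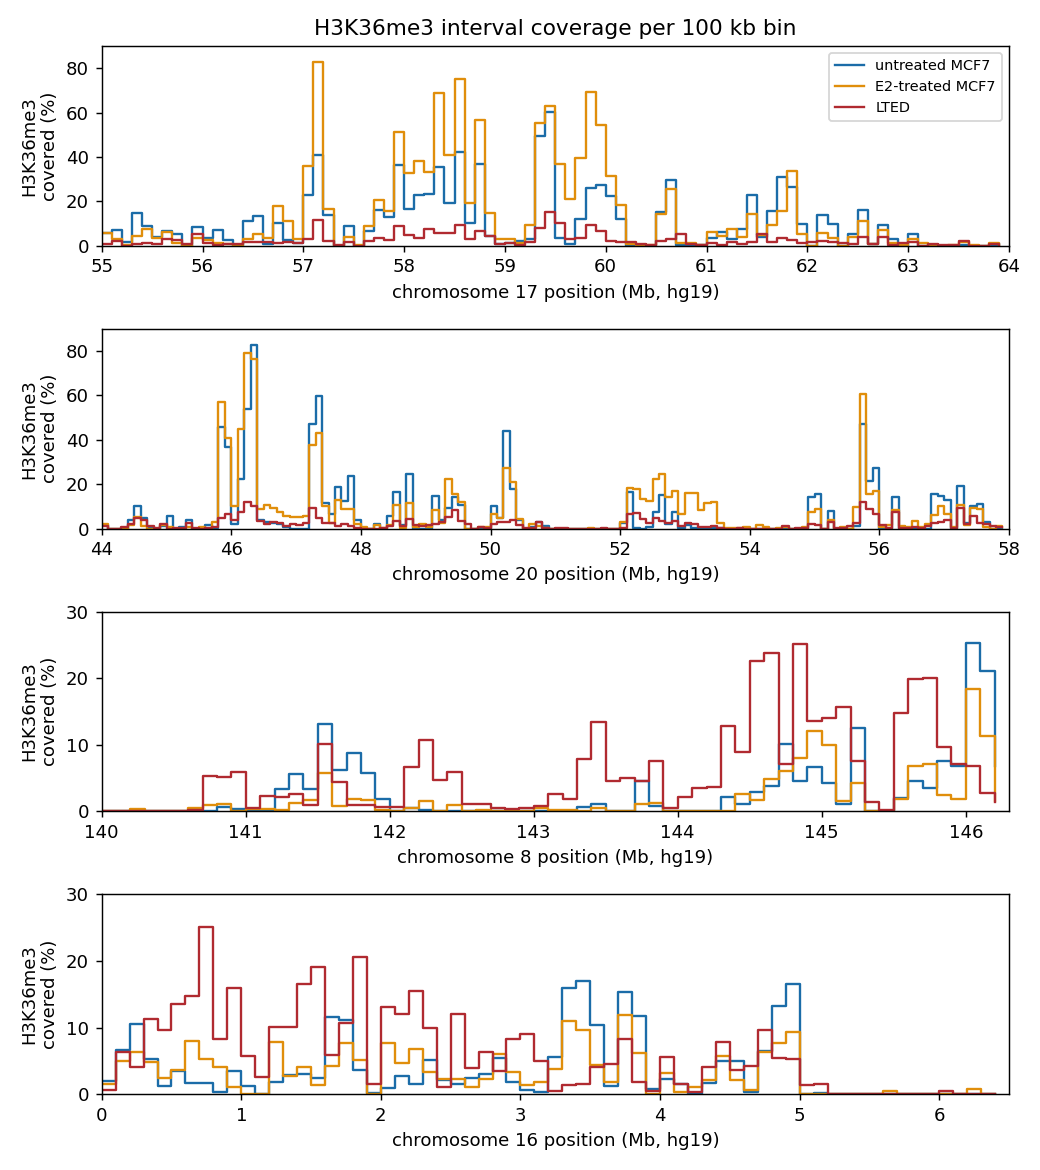
Percentage of each 100 kb bin covered by H3K36me3 intervals (vertical axes) against position in Mb in hg19 (horizontal axes) for stretches of chromosomes 17, 20, 8 and 16, with 1 line per list and a narrower vertical range for chromosomes 8 and 16. Untreated and E2-treated MCF7 reached 82.7% and 76.3% in a bin of chromosome 20 where LTED had 10.3%, whereas LTED reached 25.1% in a bin of chromosome 16 where they had 1.70% and 5.24%.

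The 10 largest gains in LTED were below the limit of 25 points and are given as values. The first was at 700001 to 800000 on chromosome 16 (hg19), with 1.70% in untreated MCF7, 5.24% in E2-treated MCF7 and 25.1% in LTED. Chromosome 16 also had bins at 1500001 to 1600000 (2.45%, 1.39% and 19.1%) and 1800001 to 1900000 (3.62%, 5.13% and 20.6%). On chromosome 8 the bins lay close together, at 144500001 to 144600000 (2.90%, 1.66% and 22.5%), 144600001 to 144700000 (3.77%, 4.83% and 23.8%) and 144800001 to 144900000 (4.64%, 8.08% and 25.1%). The others were on chromosome 7 at 1500001 to 1600000 (3.18%, 7.58% and 24.1%), on chromosome 9 at 140300001 to 140400000 (0.591%, 2.43% and 17.8%), on chromosome 14 at 105900001 to 106000000 (3.55%, 4.94% and 19.7%), and on chromosome 10 at 134500001 to 134600000 (1.88%, 1.02% and 16.3%).

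At a limit of 10 points, added after the data were seen, 49 bins were higher in LTED than in both MCF7 lists and 98 were lower. The distance to chromosome ends was also examined only then. Of the 49 higher bins, 45 (91.8%) lay within 10 Mb of a chromosome end, at a median of 1.29 Mb. Of the 98 lower bins, 24 (24.5%) did so, at a median of 20.5 Mb, and of all bins with H3K36me3 18.0% did so, at a median of 31.5 Mb. The 49 higher bins were also among the most covered in LTED, at a mean percentile of 99.85. They were not compared with other bins of high LTED coverage. The values thus cannot tell a place of change from a place of high LTED coverage. Chromosome 8 held 9 of the higher bins and chromosomes 16 and 19 held 6 each. Chromosome 17 held 27 of the lower bins, chromosome 19 held 18 and chromosome 20 held 16.

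The comparison of E2-treated with untreated MCF7 asked what E2 changed within 45 minutes, and also showed how far 2 lists of the same line differed. By at least 25 points, 7 bins were higher after E2 and 2 were lower. All 7 higher bins were on chromosome 17, whose long arm is known to be amplified in MCF7 and which held 7 of the 17 bins lower in LTED. Chosen after their values were seen, the examples are the bins at 59800001 to 59900000 (26.1% to 69.2%), 57100001 to 57200000 (41.0% to 82.8%) and 58300001 to 58400000 (35.3% to 69.0%) in hg19. The 2 lower bins were at 98500001 to 98600000 on chromosome 7 (47.6% to 16.98%) and at 52500001 to 52600000 on chromosome 15 (36.4% to 10.6%). The balance turned with the setting. With intervals within 1 kb joined, 5 bins were higher and 24 lower, at a limit of 10 points 34 were higher and 86 lower, without chromosomes 17 and 20 0 were higher, and with lists of matched covered length 0 were lower.

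**Figure D2:**
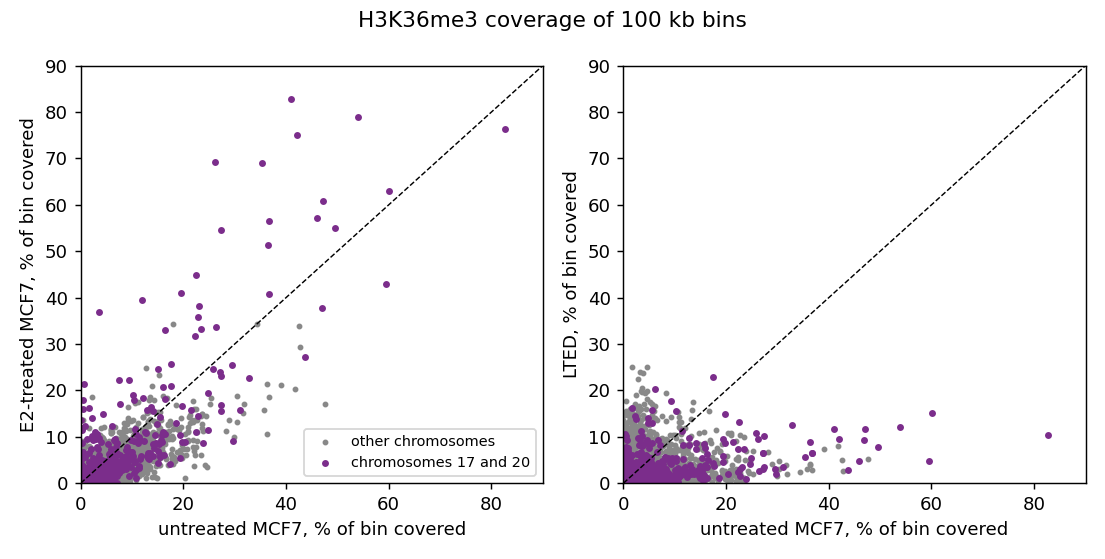
H3K36me3 coverage of 100 kb bins in percent, untreated MCF7 on the horizontal axes against E2-treated MCF7 (left) and LTED (right), with 1 point per bin, bins of chromosomes 17 and 20 in purple and the dashed line marking equal coverage. E2-treated MCF7 rose with untreated MCF7 (Pearson 0.800), while LTED stayed at or below 25.1% in every bin (Pearson 0.392).

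FAIRE asked where chromatin was open in LTED. Of replicate 1 sites, 53.3% (52.9 to 53.8%) met a replicate 2 site, and of replicate 2 sites 39.0% (38.7 to 39.4%) met a replicate 1 site. The first share was 13.6 times that of random placement on the same chromosome and 7.04 times that of local shifts (permutation p = 0.0099). Shared sites had median scores of 126 and 118 in replicates 1 and 2, against 66.4 and 65.1 for sites of a single replicate. The 23243 merged regions of both replicates covered 26.9 Mb.

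Open chromatin coincided with H3K4me2. Of the FAIRE sites of both replicates, 39.1% (38.5 to 39.8%) met an H3K4me2 region, 15.4 times the share after random placement and 7.38 times that after local shifts (permutation p = 0.0099). The share was 28.3% for all sites of replicate 1 and 17.4% for all sites of replicate 2, and 9.85% of the sites of both replicates had at least 50% of their length in an H3K4me2 region. At shared sites, which overlap each other by definition, the shares were 37.9% and 37.4%. At unshared sites they differed, with 17.3% (16.8 to 17.9%) in replicate 1 and 4.63% (4.42 to 4.85%) in replicate 2.

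PBX1 was examined for its place in open and H3K4me2-marked chromatin. Of the 25483 summits, 16.4% (15.9 to 16.8%) lay at a FAIRE site of both replicates and 14.7% (14.3 to 15.1%) at an H3K4me2 region. These shares were 13.2 and 12.1 times those of random placement, and 6.90 and 5.32 times those of local shifts (permutation p = 0.0099 for each). Most summits, 19387 or 76.1%, lay at neither, with a median height of 15. Summits at FAIRE without H3K4me2 numbered 2348 (median height 22), those at both features 1827 (20), and those at H3K4me2 alone 1921 (17). With only the stricter part of the summits by height, 24.8% lay at FAIRE sites. Seen from the whole FAIRE sites, 32.2% (31.3 to 33.2%, 2932 of 9098) of those with H3K4me2 held a PBX1 summit. Of those without, 8.65% (8.19 to 9.12%, 1223 of 14145) did. By whole site, most FAIRE sites holding a summit thus had H3K4me2. These groups of sites were not matched for width or score, and wider sites meet both lists more readily. Of the stricter part of the FAIRE sites by score, 50.8% met H3K4me2.

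**Figure D3:**
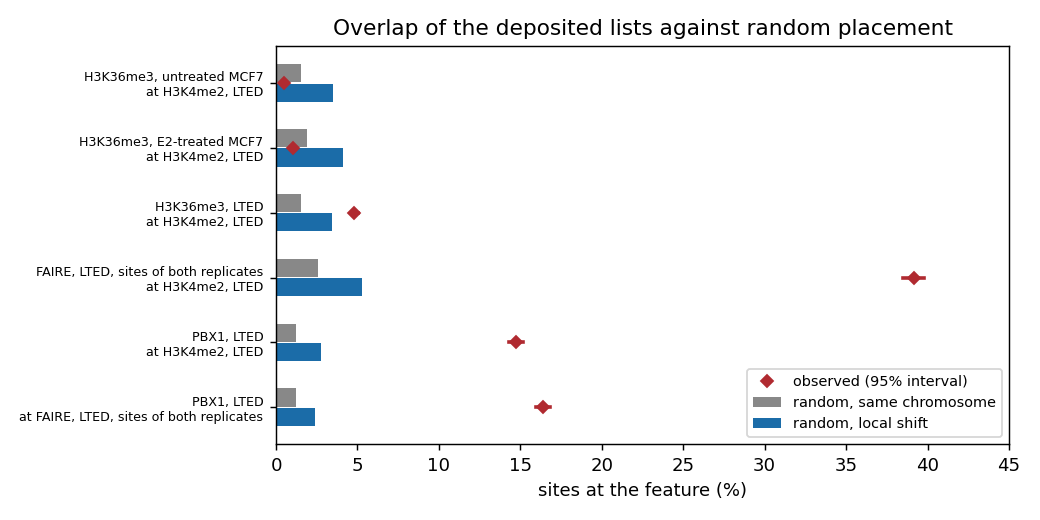
Percentage of sites (horizontal axis) meeting a feature for 6 pairs of lists (vertical axis), with diamonds for the observed share and its exact 95% interval, and bars for the mean of 100 random placements on the same chromosome (grey) or local shifts (blue). FAIRE sites at H3K4me2 (39.1%) and PBX1 summits at H3K4me2 (14.7%) and FAIRE (16.4%) exceeded both backgrounds, and H3K36me3 of untreated MCF7 at H3K4me2 (0.510%) fell below both.

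Higher PBX1 summits lay in open chromatin more often. The share at FAIRE sites of both replicates rose from 6.04% at heights of 9 to 12, through 25.7% at 20 to 29 and 58.8% at 50 to 99, to 76.0% (71.5 to 80.1%, n = 396) at 100 and above. The share at H3K4me2 rose from 8.73% to 30.5% (27.1 to 34.1%) at heights of 50 to 99 and was 20.2% (16.4 to 24.5%) at 100 and above. Only H3K4me2 within 100 bp of the summit was counted, and no other window was run by height. The lower share in the highest class thus cannot place these summits outside H3K4me2-marked chromatin. The 5 highest summits were at 58754773 on chromosome 17 (hg19, height 779), 47604495 on chromosome 21 (776), 45973431 on chromosome 17 (691), 10828555 on chromosome 19 (626) and 61627656 on chromosome 17 (585). The first lay at H3K4me2 without FAIRE, the one on chromosome 21 at both, and the others at FAIRE sites of both replicates without H3K4me2 in the window. The first also lay in the bin at 58700001 to 58800000, among the largest losses of H3K36me3 in LTED. No FAIRE site of either replicate lay anywhere in that bin, so its lack of FAIRE is not particular to the summit.

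**Figure D4:**
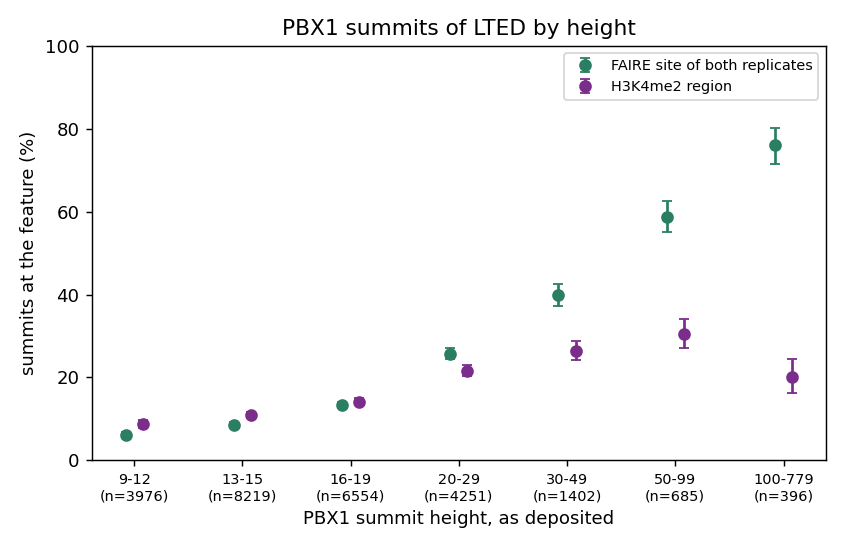
Percentage of PBX1 summits of LTED at a FAIRE site of both replicates (green) or an H3K4me2 region (purple) against classes of summit height, with exact 95% intervals and the number of summits under each class. The FAIRE share rose from 6.04% to 76.0%, and the H3K4me2 share peaked at 30.5% and was 20.2% in the highest class.

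H3K36me3 was set against the LTED features as well. Intervals of untreated MCF7 met LTED H3K4me2 regions in 0.510% of cases and those of E2-treated MCF7 in 1.04%, which was 0.145 and 0.252 times the share after local shifts. LTED intervals did so in 4.81% (4.62 to 5.01%), 1.39 times the share after local shifts (permutation p = 0.0099). PBX1 summits met H3K36me3 intervals of LTED in 5.26% of cases, 1.59 times the share after local shifts, those of untreated MCF7 in 5.64% (1.42 times) and those of E2-treated MCF7 in 2.72% (1.13 times). These shares pool all heights. From heights of 9 to 12 to those of 100 and above, the untreated share went from 5.21% to 1.52% (0.558 to 3.27%). The LTED share went from 5.99% to 9.09% and the E2-treated share from 2.21% to 5.81%. Local shifts were not run by height. H3K4me2 of MCF7 was not analysed here.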

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

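No test in this part was chosen after the result was seen. The mitochondrial genome, which has no histones and was outside the comparisons, held 5 H3K36me3 intervals in untreated MCF7, 6 in E2-treated MCF7 and 2 in LTED.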

How the results depend on the processing

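The limit of 10 points and the removal of chromosomes 17 and 20 were tests chosen only after the data were seen. Alternatives based on genes, gene lists or distance to genes were not run, for want of an annotation in hg19. Unknown read depth limits every comparison of lists, and the causes of the changes below were not tested unless the setting itself gives them. Of the values under alternatives, 40 counted as in place and 40 as moved. In place meant within the 95% interval for shares of H3K36me3 intervals, within 1.5 times for counts of bins, and still above random placement for the tested overlaps, whatever the size of the share, so that FAIRE at H3K4me2 fell to 9.85% when 50% of the site had to be covered. All overlaps among FAIRE, PBX1 and H3K4me2 stayed above random placement under every alternative run. With each FAIRE replicate alone, PBX1 at FAIRE ranged from 17.5 to 19.9% and FAIRE at H3K4me2 from 17.4 to 28.3%. No paired analysis was possible because only FAIRE had replicates and it had 1 condition.

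LTED intervals meeting untreated MCF7 moved from 11.0% to 7.18% at matched length, 6.77% for the stricter part of each list by score, 13.1% with intervals within 1 kb joined and 10.1% without chromosomes 17 and 20. Those meeting E2-treated MCF7 moved from 9.83% to 8.94%, 6.80%, 10.8% and 8.88% under these settings in turn, and E2-treated intervals meeting untreated ones from 36.1% to 27.5%, 31.4%, 35.2% and 34.3%. E2-treated against untreated stayed highest in each, but the order of the other pairs turned at matched length (7.18 against 8.94%) and lay within 6.77 to 6.80% for the stricter part.

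With 50 kb bins, LTED against untreated MCF7 had 7 gained and 98 lost bins, E2 against untreated 22 and 18, and LTED against both lists 4 and 32. With 500 kb bins there was 1 lost bin against untreated MCF7 and 1 against both lists, and 1 gained and 0 lost with E2. Joining intervals gave 102 lost bins against untreated MCF7, 28 against both, and 5 gained and 24 lost with E2. Matched length gave 0 lost with E2, and 22 lost in LTED against untreated MCF7. At 10 points, LTED against untreated MCF7 had 73 gained and 288 lost, E2 34 and 86, and LTED against both 49 and 98, as a lower limit must give more. Without chromosomes 17 and 20, 15 bins were lost against untreated MCF7, 3 against both, and 0 gained with E2. With both changes together, 66 were gained and 217 lost against untreated MCF7, 46 gained and 55 lost against both, and 5 gained and 70 lost with E2. Since LTED coverage reached at most 25.1% in any 100 kb bin, counts of 0 gained bins at 25 points say nothing on the direction of change.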

Other observations

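In this part, the tests of list-wide coverage, of the control library, of H3K4me2 reads and of open chromatin, and the counts per window, were chosen only after a result was seen. In the lists of all 7 samples together, 23 of 255730 merged regions held an interval of every list. Among them, chosen after the values were seen, were regions at 127567068 to 127571578 on chromosome 8, at 53342977 to 53347618 on chromosome 12 and at 47310567 to 47323686 on chromosome 20 (hg19). The windows of 1 Mb with the most FAIRE sites of replicate 2 alone lay on chromosome 14 at 41000001 to 44000000 (94, 95 and 84 sites), on chromosome 3 at 162000001 to 166000000 (80, 92, 94 and 83), on chromosome 1 at 195000001 to 196000000 (84) and 198000001 to 199000000 (78), and on chromosome 8 at 111000001 to 112000000 (82). The window with 78 sites held 17 H3K4me2 regions and the others 1 to 8, against a median of 16 over 2881 windows. These windows were also rich in shared sites (15 to 48) and in sites of replicate 1 alone (14 to 27), each with a median of 6 over all windows. Across windows, the Spearman correlation with the number of H3K4me2 regions was 0.677 for shared FAIRE sites, 0.425 for sites of replicate 1 alone and 0.0132 for sites of replicate 2 alone.

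The list-wide test first took bins by the untreated list, which by itself favours a lower value in LTED and gave 97.8%, so bins were then taken by the E2-treated list, which is of the same line and favours it too. The tests of H3K4me2 reads and open chromatin replaced earlier ones that had left both explanations open. Those were a ratio of median H3K4me2 scores of 1.34 and a ratio of 1.08 over local shifts at FAIRE sites. The first is on an unknown scale, and the regions met were wider (460 bp against 318 bp for all). The bounds of the later tests were also set by then, and for H3K4me2 reads with the shares themselves known. The comparison with MCF7 was added last. Without it the later tests had counted both explanations as excluded, and with it both stayed open.

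The first pattern was the 17 bins lower in LTED than in both MCF7 lists, 7 of them on chromosome 17 and 7 on chromosome 20, whose long arms are known to be amplified in MCF7. A loss of the extra copies in LTED is a candidate explanation, and would leave these bins with no more copies than the rest. PBX1 summits of LTED inside the bins were 2.22 times as high as outside (0.813 to 4.75), too few at 8 summits to decide. Ratios of median scores are on an unknown scale and so do not decide either. They were 1.69 (1.37 to 2.09) for H3K4me2, and 1.89 (1.12 to 3.22) and 1.72 (0.782 to 4.17) for FAIRE replicates 1 and 2. For H3K36me3 they were 0.991 (0.888 to 1.07) in LTED, 2.14 (1.99 to 2.31) in untreated and 1.81 (1.69 to 1.97) in E2-treated MCF7. Median widths inside were 560 bp for H3K4me2 and 446 bp for LTED H3K36me3, against 318 and 269 bp for all. Whether scores move with width was not tested. A list that covers less of every strongly marked bin could also give the pattern and stays open. The LTED list had the smallest covered length of the H3K36me3 lists but lay in the most bins, which by itself does not decide. Of 269 bins outside chromosomes 3, 17 and 20 chosen by E2-treated coverage, 82.9% were lower in LTED than in untreated MCF7 at matched length, but a choice by the same line favours this, just as a choice by LTED coverage gives higher values in LTED (medians of 9.95% in LTED, 1.93% in untreated and 3.45% in E2-treated MCF7), so neither decides. A control library with high signal there stays open too. Of H3K4me2 regions inside, 29.2% (20.1 to 39.8%) met a FAIRE site against 32.7% outside. Among those with scores at least the median inside, the shares were 33.3% (15 of 45) and 40.3%. These shares pool bins that differ. No FAIRE site lay in 7 of the 10 with the largest losses, so regions within those could not meet one, against 2 of the 10 largest gains. Among the 7, the bin at 59400001 to 59500000 on chromosome 17 was covered by H3K4me2 at 12.6%. The 10 bins with the largest losses also held 3 PBX1 summits against 92 in the 10 with the largest gains. Over all 30359 bins there were 25483 summits, so this contrast comes largely from gain bins rich in summits. The highest summit of the list lay in one of the loss bins. A difference between LTED and MCF7 in transcription was not tested.

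The second pattern was that LTED H3K36me3 intervals met LTED H3K4me2 regions more often than after local shifts, while MCF7 intervals did so less often. Reads of the H3K4me2 library in the H3K36me3 library stay open. H3K4me2 regions of 300 to 500 bp in the third with the highest scores were met by LTED intervals 0.967 times (0.825 to 1.13) as often as those in the third with the lowest, but only 0.382 (0.217 to 0.627) and 0.333 (0.188 to 0.521) times as often by untreated and E2-treated MCF7 intervals. Enrichment of open chromatin was not excluded either. In LTED, such regions at a FAIRE site were met 0.523 times (0.441 to 0.613) as often as those without, the reverse of what it calls for. The mark can be low at such regions for other reasons, so MCF7 was set beside it. The ratios there were 0.907 (0.595 to 1.33) in untreated and 0.658 (0.404 to 0.995) in E2-treated MCF7. They rest on 35 and 27 regions met at FAIRE sites, and their intervals overlap that of LTED. Over local shifts, LTED H3K36me3 at FAIRE sites of both replicates lay at 1.08 times (1.09 for replicate 1 and 0.813 for replicate 2). In untreated and E2-treated MCF7 this was 0.274 and 0.463, a difference that leaves the explanation open. Weaker specificity of the LTED immunoprecipitation and a difference between LTED and MCF7 in the mark itself both stay open, untested.

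The third pattern was the lower share of FAIRE sites at H3K4me2 in replicate 2. Additional weak sites do not account for all of it, since with as many sites as replicate 1, taken by score, the share of replicate 2 rose from 17.4% to 21.2%, against 28.3% (27.9 to 28.7%). A different division of the sites among chromosomes does not either, since the share was lower in 23 of 23 chromosomes. Shares per chromosome cannot speak to the spread within chromosomes, which stays open. Per 1 Mb window, sites of replicate 2 alone correlated with H3K4me2 regions at Spearman 0.0132, against 0.425 for replicate 1 alone. The replicates share a condition, so the design gives no biological explanation and none was tested.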
